A study of Mus musculus with 6 samples.

How the data were processed

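RNA sequencing was deposited for 2 mouse cell lines with 3 libraries each. Per the labels' protocols, total RNA was extracted with a Maxwell RSC simplyRNA kit, messenger RNA was selected by poly(A) or ribosomal RNA was depleted, cDNA was primed with random hexamers, and the amplified product was circularised as single strands for sequencing. The submitters' processing notes name TopHat2 2.2.4, DESeq2 1.8.1 and the human build hg19, although both tables hold mouse genes; the build used for the mouse genes is not given in the sources used here, so no coordinates are printed. The deposited values are FPKM, a unit read from the values themselves since no header states it, and FPKM cannot be told apart from RPKM there.

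The 2 tables came from different pipelines. Per the file headers, the Pten_Smad4 table lists 44422 loci with assembled locus numbers, of which 25128 were 0 in every library and 1205 carried several gene names. The RM1 table lists 17268 genes by Entrez number and RefSeq transcript, of which 1682 were 0 in every library. The Pten_Smad4 columns carry no number that ties them to a replicate of the labels and are used as 3 replicates without numbers.

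Gene names were brought to RefSeq symbols of GRCm38.p6, which matched 17217 RM1 rows by gene number and 31982 of 43217 loci with a single name. Loci with several names were left out, 512 names on several loci were summed and 29 RM1 rows that shared a symbol were left out. Only the 15222 genes in both tables were compared; a gene without a row in either table was not analysed here.

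The design fixed before the data were examined was limma on log2(FPKM + 1), with camera for gene lists. It was not run, because each line sits in a table normalized separately and a test between them would test the tables as well. In its place, levels are given as mean ± SD, and 3 descriptions were chosen after the unit was seen: genes at 10 FPKM or more in every library of a line and under 1 FPKM in every library of the other; genes at least 4-fold apart (2-fold was the planned size) on log2(FPKM + 1) with no overlap between libraries, over genes with a mean of 1 FPKM or more in either line; and the median log2 ratio of each of the 21 lists fixed beforehand, as its percentile among 10000 random lists drawn from 10 bins of mean level, for lists with at least 5 such genes. A fold on this scale understates the change of low genes. A percentile describes these libraries and is not a p-value.

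The genes named follow a rule fixed before the data were examined: Pten, Smad4, Hras and Myc; from each list up to 2 members with the largest log2 ratio either way, no overlap between libraries and a mean of 5 FPKM or more in either line; and the 4 highest and 4 lowest genes over all, without predicted genes. Its condition on an adjusted p was dropped, since there was no test. Other list members given as examples were chosen after their values were seen.

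The value of 1 read was taken from the steps between low values of genes with a single transcript in GENCODE M21, where 90.4% to 92.3% of low values in Pten_Smad4 and 68.2% to 71.1% in RM1 were within 0.1 of a whole read. Differences between replicates were measured by a chi-square over genes with at least 20 reads per pair. Near-identical copies were searched with BLAST 2.17.0 for the longest coding sequence of each gene reaching 10 FPKM in a line, at 95% identity over 50% of its length. A first search with whole transcripts missed known copies of Gapdh and was replaced. Intervals are 95% Wilson intervals.

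The measures were tested on simulated data made from 9929 genes at their Pten_Smad4 levels, of which 200 were changed. Of 50 genes made 8-fold higher and 50 made 8-fold lower, 50 and 42 were called at 4-fold; among those at 2 FPKM or more in both simulated lines, 48 of 48 and 30 of 30 were. Of 50 genes made 2-fold higher and 50 made 2-fold lower, 0 were called, 0 of 9726 unchanged genes were called, and 10 of 200 random lists fell outside the central 95%. Changed genes were scored on the fold alone, without the condition on overlap. Both simulated lines had the same levels and noise, with genes varying independently and no difference between tables. The noise was a single SD for all genes, the median over genes of the SD of log2(FPKM + 1) in RM1. It did not grow at low levels, and the spread of the Pten_Smad4 libraries was not used. The simulation therefore checks the calculation and cannot show how many calls come from the tables or from genes that vary together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were other pseudocounts (0.1 and 5), no filter on low values, quantile normalization, upper-quartile and median-of-ratios scaling (planned for counts, applied to the FPKM values), genes in a single table set to 0, MHC lists without classical and Qa genes and each library left out in turn, with others added after the data were seen.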

Results

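RNA was sequenced from 2 established mouse prostate cancer cell lines, with 3 libraries each and 6 in all. Per the labels, the line called Pten_Smad4 came from the primary prostate tumour of an FVB mouse with Pten and Smad4 deleted in the prostate. RM1 is labelled as a C57BL/6 prostate line transformed by ras and myc. The labels give an age in weeks for Pten_Smad4 and a much younger age in days for RM1. Mouse strain and labelled age therefore differ together with the line. Pten_Smad4 and RM1 below mean the libraries labelled so. The deposited FPKM values summed to between 435784 and 459947 per Pten_Smad4 library and to between 451073 and 456465 per RM1 library. From the steps between low values, the Pten_Smad4 libraries held about 16730000, 8980000 and 8770000 reads and the RM1 libraries about 12860000, 13220000 and 13140000. On a 2 kb transcript, 3 reads then equalled 0.090, 0.167 and 0.171 FPKM in Pten_Smad4 and 0.117, 0.114 and 0.114 FPKM in RM1, which covers counting error only. No pair of libraries of a line was identical: at most 2.80% of values above 0 were equal. The chi-square per gene had a mean of 2.09 to 2.32 and a median of 0.595 to 0.685 between Pten_Smad4 pairs, and a mean of 2.05 to 2.94 and a median of 0.745 to 0.929 between RM1 pairs, against 1 and 0.455 for counting noise alone. Each library was counted as a replicate because the labels list it as one. Repeat libraries of 1 culture can also exceed counting noise and nothing in the labels says that the cultures were separate, so the errors below may be technical.

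Each line was deposited in a table of its own, made over a different gene annotation and normalized separately. Levels of the lines are therefore set side by side as mean ± SD (n = 3) without a test between lines. Any difference between the lines is also a difference between the tables, the mouse strains and the labelled ages. The tables shared 15222 genes, of which 8796 were at 1 FPKM or more in all 6 libraries. Among 10469 genes with a mean of at least 1 FPKM in either line, the median log2 ratio of Pten_Smad4 to RM1 was 0.44 on the log2(FPKM + 1) scale, with an SD of 1.41 across genes.

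The genes named in the labels were considered first. Myc, which encodes the growth-promoting transcription factor, was at 83.4 ± 4.17 FPKM in Pten_Smad4 and 9.20 ± 0.771 FPKM in RM1, the line labelled as myc-transformed. Hras, which encodes a small GTPase upstream of ERK, was at 43.3 ± 4.47 FPKM in Pten_Smad4 and 122 ± 5.80 FPKM in RM1. Transcript of the tumour suppressor Pten was listed at 10.4, 12.3 and 10.6 FPKM in the Pten_Smad4 libraries, against 17.8, 17.4 and 18.0 FPKM in RM1. Smad4, which encodes the shared mediator of TGF-beta and BMP signalling, was at 33.6, 48.0 and 32.3 FPKM in Pten_Smad4 and at 36.5, 36.9 and 37.0 FPKM in RM1, so its deposited values overlapped; its log2 ratio of 0.02 was -0.44 after median-of-ratios scaling. The deleted parts of Pten and Smad4 are not given in the labels and a gene-level value sums over exons, so these levels do not check the genotype; likewise a transgene that is not of mouse sequence need not be counted at Hras or Myc.

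Many genes were listed in 1 line and nearly missing from the other. In Pten_Smad4, 128 genes reached 10 FPKM in every library while staying under 1 FPKM in every RM1 library, and 84 genes did the reverse. The counts were 107 and 99 after upper-quartile scaling, 104 and 99 after median-of-ratios scaling and 94 and 107 after quantile normalization, where RM1 had more. They were 675 and 736, with RM1 again having more, when genes of a single table were set to 0 in the other. That setting also put at 0 genes whose Pten_Smad4 loci were left out for carrying several names, such as Eef1a1 and Ftl1. The count for RM1 therefore includes genes that the Pten_Smad4 table does list. At a difference of at least 4-fold with no overlap between libraries, 759 of 10469 genes were higher in Pten_Smad4 and 506 in RM1. These shares over all genes are the background for the 4-fold counts of each list below. Chance alone leaves 10% of genes without overlap between 3 libraries and 3 others, a share that leaves the 4-fold condition aside. Relative to the median of all genes the split was 463 and 672, after quantile normalization 519 and 599, after upper-quartile scaling 547 and 614 and after median-of-ratios scaling 512 and 636, so which line had more of the higher genes depended on the scaling. At the 2-fold threshold the counts were 2861 and 1114, with 1636 and 1757 relative to the median, 1906 and 1625 after upper-quartile scaling and 1753 and 1779 after median-of-ratios scaling. Without genes that have a near-identical copy elsewhere, 732 genes in place of 759 were at least 4-fold higher in Pten_Smad4 and 296 in place of 506 in RM1. The scaled counts above keep the genes with copies, and scaling without them was not run. The genes farthest apart toward Pten_Smad4, beyond those named from the lists below, were Slc43a3, a membrane transporter, at 205 ± 11.1 against 0.020 ± 0.017 FPKM, the homeobox gene Rhox5 at 304 ± 9.23 against 1.11 ± 0.336 FPKM, Bgn, which encodes the matrix proteoglycan biglycan, at 380 ± 17.0 against 1.70 ± 0.304 FPKM, and Mgst1, a microsomal glutathione transferase, at 151 ± 5.21 against 0.113 ± 0.133 FPKM. Toward RM1 they were Rpl29, Rps16, Rps23 and Rpl31-ps12, at 749 ± 18.4, 1058 ± 59.1, 2196 ± 65.4 and 410 ± 19.7 FPKM in RM1. Each of these genes, of which Rpl31-ps12 is a pseudogene, has near-identical copies, 30, 3, 14 and 12 of them. The rows of the copies summed to 23, 993, 564 and 209 FPKM in the Pten_Smad4 table. Rows of the copies in the RM1 table were not examined, so the RM1 values may also hold reads of the copies.

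**Figure D1:**
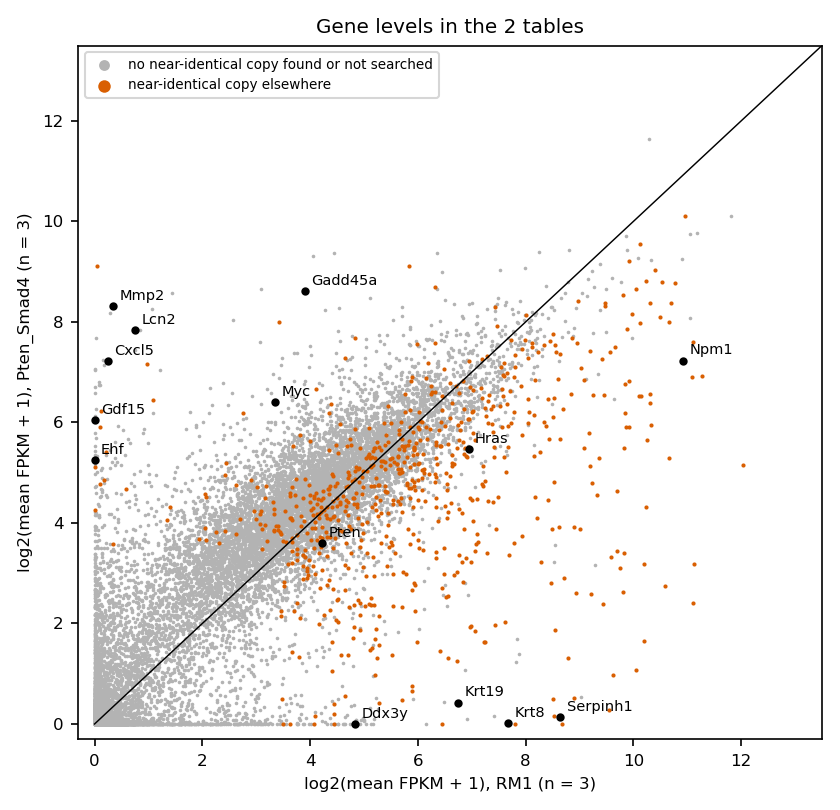
Mean level of each shared gene in RM1 (x axis) and Pten_Smad4 (y axis), both as log2(mean FPKM + 1) over 3 libraries. Orange points have a near-identical copy elsewhere in the genome and the line marks equal levels. Mmp2, Lcn2, Cxcl5, Gdf15 and Ehf lie along the Pten_Smad4 axis, Krt8, Krt19, Serpinh1 and Ddx3y along the RM1 axis, and many orange points lie below the line at high RM1 levels.

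Epithelial genes were sparse in both lines, with 3 of 29 measured epithelial junction and regulator genes at 1 FPKM or more in Pten_Smad4 and 3 in RM1. Ehf, an epithelial ETS-family transcription factor, was at 36.9 ± 2.38 FPKM in Pten_Smad4 and listed at 0 in each RM1 library. Jup, which encodes the junction protein plakoglobin, was at 1.53 ± 0.267 and 14.7 ± 0.661 FPKM. The list's median log2 ratio of -0.33 was within the central 95% of random lists matched on level. Luminal prostate genes split: of 14 members with a ratio, 5 were at least 4-fold higher in Pten_Smad4 and 3 in RM1. The luminal keratin gene Krt8 was listed at 0.036, 0 and 0 FPKM in Pten_Smad4 and at 204 ± 6.67 FPKM in RM1, Krt19 at 0.345 ± 0.240 and 107 ± 4.76 FPKM, and Krt18, whose protein pairs with that of Krt8 in filaments, at 52.7 ± 1.92 and 201 ± 5.99 FPKM. Acpp, which encodes prostatic acid phosphatase, was at 39.7 ± 0.595 against 0.153 ± 0.015 FPKM, and the androgen receptor gene Ar at 1.48 ± 0.185 against 11.2 ± 1.19 FPKM. The list's median of 1.17 lay at percentile 99.15 of random lists, but fell inside the central 95% under 4 settings. It lay at 53.87 without the filter on low values, at 90.98 with genes of a single table set to 0, at 96.29 with a pseudocount of 5 and at 96.20 with loci of several names given to their protein-coding gene. Of 7 basal epithelial genes with a ratio, 1 was at least 4-fold higher in Pten_Smad4 and 0 in RM1. Bnc1, a basal epithelial zinc-finger gene, was at 6.01 ± 1.45 against 0.20 ± 0.070 FPKM, and Pdpn, which encodes podoplanin, was at 25.4 ± 1.59 against 89.2 ± 4.82 FPKM. The basal list lay at percentile 97.19.

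Of 25 measured mesenchymal genes, 18 were at 1 FPKM or more in Pten_Smad4 and 12 in RM1. Vim, which encodes vimentin, was at 854 ± 35.8 FPKM in Pten_Smad4 and 2123 ± 29.9 FPKM in RM1. Of 18 mesenchymal genes with a ratio, 7 were at least 4-fold higher in Pten_Smad4 and 1 in RM1. Mmp2, a gelatinase gene, was at 318 ± 11.0 against 0.270 ± 0.072 FPKM, and Dcn, the gene of the matrix proteoglycan decorin, was at 288 ± 16.9 against 0.213 ± 0.075 FPKM. The collagen cross-linking enzyme gene Lox was at 131 ± 1.62 against 0.007 ± 0.012 FPKM. Sparc, a matrix glycoprotein gene, went the other way at 81.1 ± 4.64 against 361 ± 11.9 FPKM. The mesenchymal list member S100a4 was at 1343 ± 102 FPKM in RM1 but was not among the genes compared, so it has no ratio. Of 23 collagen and matrix genes with a ratio, 11 were at least 4-fold higher in Pten_Smad4, among them Col1a2 at 140 ± 3.28 against 0.133 ± 0.021 FPKM, and 5 in RM1. Serpinh1, which encodes the collagen chaperone HSP47, was at 0.10 ± 0.102 against 400 ± 15.5 FPKM, the basement membrane gene Nid1 at 0.109 ± 0.122 against 169 ± 7.29 FPKM, and Thbs1, which encodes thrombospondin-1, at 8.36 ± 0.340 against 367 ± 15.5 FPKM. The list medians of 0.96 each lay at percentiles 99.19 and 99.06; the matrix list moved to 73.13 without the filter on low values, and the mesenchymal list to 95.30, inside the central 95%, with genes of a single table set to 0.

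TGF-beta and BMP target genes went both ways, with 2 of 24 at least 4-fold higher in Pten_Smad4 and 5 in RM1, and their median lay at percentile 54.77. Ltbp2, which encodes a member of the latent TGF-beta binding protein family, was at 103 ± 3.69 against 0.007 ± 0.012 FPKM. The BMP-responsive inhibitor gene Id3 was at 4.96 ± 0.987 against 121 ± 5.99 FPKM, Id1 at 87.3 ± 3.36 against 68.8 ± 5.11 FPKM, and Atoh8 was listed at 0 in each Pten_Smad4 library against 15.2 ± 0.641 FPKM. YAP-TAZ targets lay at percentile 51.04, with 2 of 21 at least 4-fold higher in either line. Arhgef17, a Rho exchange factor gene, was at 0.169 ± 0.049 against 17.5 ± 0.857 FPKM, and the forkhead gene Foxf2 at 18.7 ± 0.147 against 1.07 ± 0.147 FPKM.

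RAS-ERK output genes were at 1 FPKM or more in both lines for 26 and 27 of 27 members, and the median log2 ratio of 0.06 lay at percentile 23.35. The ERK phosphatase gene Dusp6 was at 67.5 ± 1.5 and 103 ± 0.288 FPKM, and Etv4 at 76.8 ± 4.88 and 44.6 ± 1.72 FPKM. At least 4-fold higher in Pten_Smad4 were 3 members, among them the early-response gene Ier3 at 310 ± 18.6 against 22.2 ± 0.546 FPKM and Bmp2, a BMP ligand gene, at 66.1 ± 3.42 against 5.72 ± 0.511 FPKM. MYC targets in ribosome biogenesis and growth lay at the other end, at percentile 0.03 with a median of -0.29, although Myc itself was the higher in Pten_Smad4; 0 of 43 were at least 4-fold higher in Pten_Smad4 and 4 in RM1. Fbl, which encodes fibrillarin, was at 2.11 ± 0.607 against 151 ± 6.74 FPKM, but 2 copies of it summed to 160 FPKM in the Pten_Smad4 table. Npm1, which encodes nucleophosmin, was at 149 ± 8.69 against 1939 ± 35.0 FPKM; of its 3 copies, 1 had a row in that table, at 3.19 FPKM. With genes that have copies left out, the list lay at percentile 0.04.

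FOXO targets that PI3K-AKT signalling represses were at least 4-fold higher in Pten_Smad4 for 5 of 22 members and in RM1 for 0, at percentile 93.84. Gadd45a, a stress-response gene, was at 389 ± 20.8 against 14 ± 2.46 FPKM and the transcriptional repressor gene Bcl6 at 28.0 ± 0.816 against 3.32 ± 0.334 FPKM. Targets of p53 lay at percentile 99.98 with a median of 1.12, and 7 of 25 were at least 4-fold higher in Pten_Smad4 and 1 in RM1. Gdf15, which encodes a stress-induced cytokine, was at 65.0 ± 1.22 FPKM against 0 in each RM1 library, and Trp53inp1 at 95.6 ± 1.15 against 8.62 ± 0.304 FPKM. Mdm2, which encodes the ligase that degrades p53, was at 277 ± 13.2 against 51.3 ± 2.11 FPKM, and Cdkn1a, which encodes p21, at 228 ± 10.4 against 103 ± 3.80 FPKM. Mitosis and proliferation genes lay at percentile 0.00 with a median of -0.73, and 0 of 35 were at least 4-fold higher in Pten_Smad4 and 3 in RM1. The mitotic cyclin gene Ccnb1 was at 17.4 ± 0.778 against 112 ± 4.68 FPKM; of its 3 copies, 1 had a row in the Pten_Smad4 table, at 5.83 FPKM. The kinesin gene Kif20a was at 13.9 ± 0.664 against 75.7 ± 1.35 FPKM, with an overlapping gene at 30.3 FPKM in the Pten_Smad4 table. The replication gene Mcm2, in the same list, was at 109 ± 2.87 against 40.0 ± 1.41 FPKM.

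Chemokines and cytokines stood farthest from random lists, at percentile 100 with a median log2 ratio of 1.94: 14 of 31 were at least 4-fold higher in Pten_Smad4 and 1 in RM1. Lcn2, which encodes the iron-carrier protein lipocalin-2, was at 228 ± 10.7 against 0.690 ± 0.061 FPKM. Among neutrophil-attracting chemokine genes, Cxcl5 was at 148 ± 0.911 against 0.190 ± 0.123 FPKM, Cxcl1 at 137 ± 10.8 against 14.8 ± 1.76 FPKM and Cxcl2 at 33.3 ± 0.976 against 0.213 ± 0.012 FPKM. Csf3, which encodes G-CSF, was at 54.3 ± 1.17 FPKM against 0 in each RM1 library. Il33 was at 40.0 ± 1.86 against 0.487 ± 0.186 FPKM and Vegfa, the angiogenic factor gene, at 354 ± 18.3 against 33.7 ± 3.78 FPKM. The monocyte chemokine gene Ccl2 was at 98.7 ± 4.38 against 179 ± 21.4 FPKM, and Mif was the member at least 4-fold higher in RM1, at 93.2 ± 4.14 against 455 ± 17.9 FPKM.

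Interferon-response genes were expressed in both lines, at 1 FPKM or more for 34 and 33 of 34 members, with 1 member at least 4-fold higher in each line. Cxcl10, an interferon-induced chemokine gene, was at 29.6 ± 2.72 against 4.15 ± 0.387 FPKM, and Irf7, which encodes an interferon regulatory factor, at 60.8 ± 1.57 against 262 ± 5.12 FPKM, with an overlapping gene at 25.3 FPKM in the Pten_Smad4 table. The list lay at percentile 0.05 with a median of -0.33. Of 23 class I antigen presentation genes, 2 were at least 4-fold higher in each line. H2-K1 was at 357 ± 45.5 against 403 ± 13.7 FPKM and H2-D1 at 513 ± 26.6 against 602 ± 21.7 FPKM, for genes that differ in sequence between mouse strains. The immunoproteasome gene Psmb8 was at 95.6 ± 0.252 against 4.87 ± 0.303 FPKM, and Psme2 at 9.29 ± 2.94 against 107 ± 7.19 FPKM, with a copy at 129 FPKM in the Pten_Smad4 table. The class I list lay at percentile 0.21, and at 40.02 after quantile normalization. Class II genes had 4 members with a ratio, too few for a percentile, of which 0 were at least 4-fold apart; Rfxap, a class II regulator gene, was at 13.9 ± 2.59 against 4.90 ± 0.589 FPKM and Rfxank at 4.07 ± 0.515 against 5.20 ± 0.076 FPKM. Of 21 immune checkpoint and lymphocyte ligand genes, 5 were at least 4-fold higher in Pten_Smad4 and 1 in RM1, at percentile 82.10. Nectin2 was at 36.2 ± 0.381 against 4.62 ± 0.769 FPKM, Arg1, which encodes arginase-1, was listed at 0 in each Pten_Smad4 library against 14.7 ± 0.889 FPKM, and Cd274, which encodes PD-L1, was at 3.93 ± 0.471 against 2.16 ± 0.163 FPKM.

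**Figure D2:**
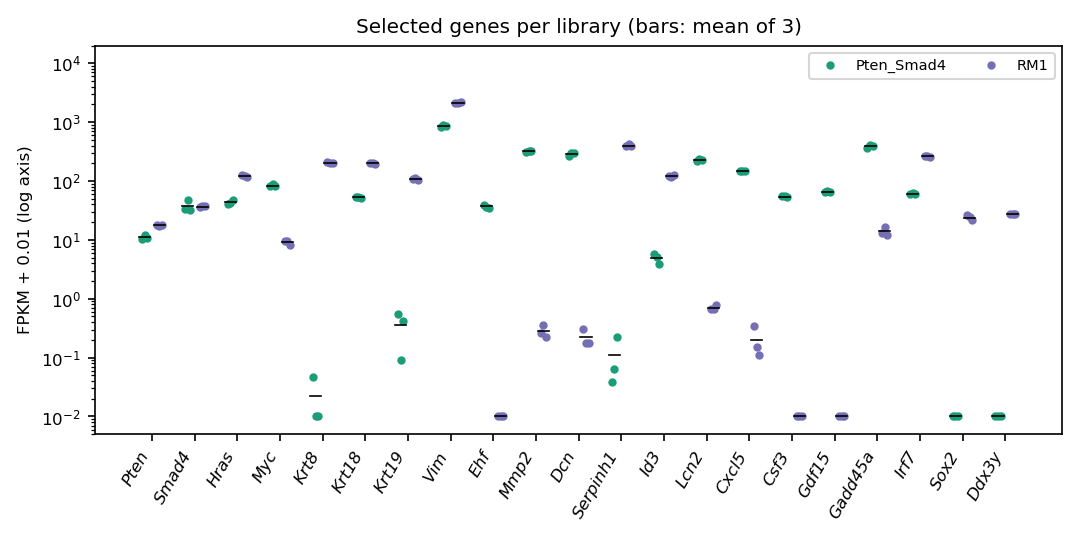
FPKM plus 0.01 on a log axis for selected genes, with 1 point per library (green Pten_Smad4, purple RM1) and a bar at the mean of 3. Myc, Mmp2, Lcn2 and Cxcl5 lie higher in Pten_Smad4 and Krt8, Serpinh1 and Sox2 higher in RM1, while Smad4 overlaps.

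Genes of neural and embryonic identity differed in single members. The labelled age is much younger for RM1, and its part in these differences was not tested because age and line coincide. Sox2, a stem-cell transcription factor gene, was listed at 0 in each Pten_Smad4 library and was at 23.9 ± 2.25 FPKM in RM1, and Foxa2, a forkhead gene, was at 0.093 ± 0.096 against 12.9 ± 1.16 FPKM. Of 5 neuroendocrine and neural genes with a ratio, 1 was at least 4-fold higher in Pten_Smad4 and 2 in RM1, at percentile 66.55. Of 17 urogenital HOX and embryonic genes, 3 were at least 4-fold higher in Pten_Smad4 and 1 in RM1, although the median of -0.26 lay at percentile 1.29. The RNA-binding protein gene Igf2bp3 was at 0.053 ± 0.027 against 29.7 ± 1.10 FPKM, with an overlapping gene at 35.8 FPKM in the Pten_Smad4 table, and Wnt5a, a noncanonical Wnt ligand gene, was at 19.3 ± 0.729 against 0.057 ± 0.081 FPKM. Leukocyte and endothelial markers were largely missing, with 3 of 17 measured members having a ratio: the calcium-binding protein gene S100a8 at 47.2 ± 4.00 against 0.570 ± 0.494 FPKM, Cd14 at 14.2 ± 0.726 against 6.06 ± 0.157 FPKM and Flt1 at 2.85 ± 0.272 against 5.79 ± 0.227 FPKM. The Y-linked genes Ddx3y and Eif2s3y were listed at 0 in each Pten_Smad4 library and at 27.5 ± 0.316 and 35.0 ± 0.590 FPKM in RM1; Kdm5d and Uty were also listed at 0 in Pten_Smad4, against 7.71 ± 0.153 and 8.85 ± 0.147 FPKM.

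**Figure D3:**
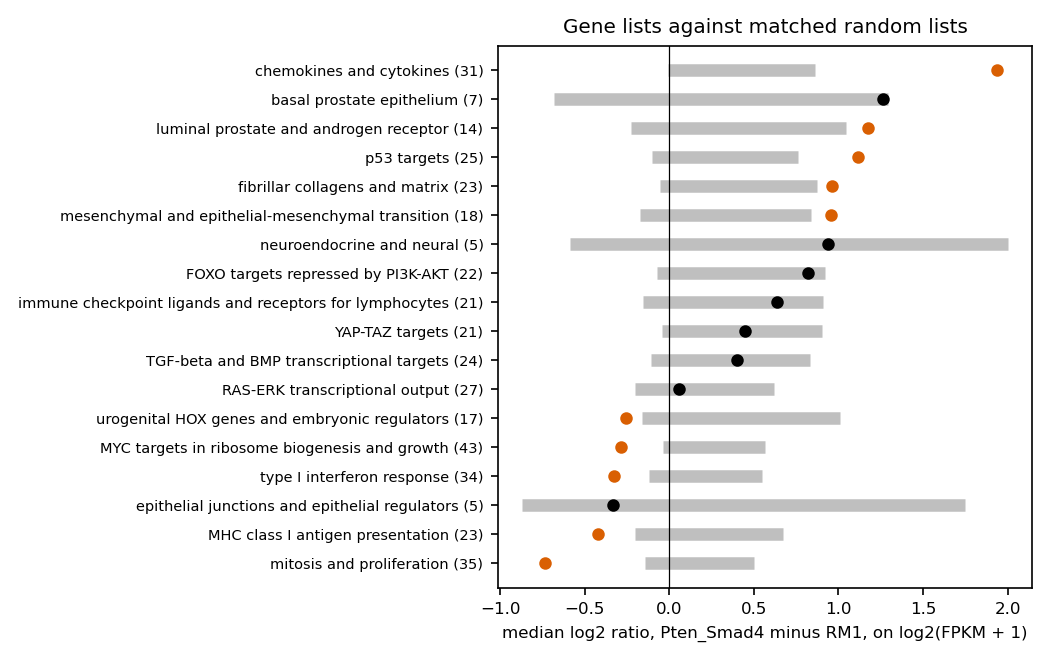
Median log2 ratio of Pten_Smad4 to RM1 on log2(FPKM + 1) for each gene list with at least 5 members, with the number of members in parentheses. Grey bars span the central 95% of 10000 random lists matched on level and orange points lie outside them, 5 above and 5 below.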

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

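The test of copies for Krt8 and Krt19 was chosen after the result was seen; the criteria for the others were written before the values they measure, except that the copy criterion was reworded from transcripts to coding sequences after a first search.

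Rows outside the genes compared carried strong signal. In the Pten_Smad4 table these were the merged locus of the mitochondrial genes at 8195 FPKM, the pseudogene Gm3788 at 4046 FPKM and the locus of Ftl1 and Gm22133 at 1852 FPKM. In the RM1 table they were Eef1a1 at 7169 FPKM, Rpl23a at 2071 FPKM and Hspa8 at 1856 FPKM. Some had a counterpart that was left out for carrying several names: Eef1a1 shared a locus with Gm26377 at 1159 FPKM in the Pten_Smad4 table, and Ftl1 was at 1238 FPKM in RM1. In all, 1201 such rows in the Pten_Smad4 table and 658 in the RM1 table were at 10 FPKM or more in every library.

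The 84 genes present in RM1 and nearly missing from Pten_Smad4 were weighed against the counting. Of 83 searched, 20.48% had a near-identical copy (95% Wilson interval 13.20% to 30.38%), against 7.81% of the genes present in Pten_Smad4 and 9.45% of the other genes searched, which argues against shared reads as the cause of the whole set. For the 17 with a copy, the copies summed to 10 FPKM or more in the Pten_Smad4 table in 58.82% (95% Wilson interval 36.01% to 78.39%). The missing reads of these genes may have been counted at the copies. The same share was 52.15% for other genes with copies, inside that interval, so the share cannot tell this cause from others. Rows of the copies in the RM1 table were not examined. An overlapping gene at 10 FPKM or more in the Pten_Smad4 table was found for 21.69% of the set (95% Wilson interval 14.18% to 31.70%). In that same table the share was 7.03% for the genes present in Pten_Smad4 and 13.25% for the other genes searched. Overlapping rows in the RM1 table were not examined. The upper bound argues against overlapping rows found by name as the cause of most of the set. It cannot exclude overlap, since an overlapping gene named otherwise in the Pten_Smad4 table would be missed. Overlap stays open for the genes that have it. Nedd4, at 0.453 against 524 FPKM, was among these genes with an overlapping row at 233 FPKM. With loci of several names given to their one protein-coding gene, 83 of the 84 genes stayed in the set. Loci with several protein-coding genes were still left out there. For the remaining genes, a difference between the lines and other differences between the 2 pipelines stay open and untested, because line and table coincide.

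Krt8 and Krt19 were near 0 in Pten_Smad4 while Krt18 was at 52.7 FPKM. For Krt19, 0 near-identical copies were found, which argues against reads of the gene counted at its copies. For Krt8, the 1 copy found had no row in that table (0 copies with a row), so reads of the gene counted at its copies cannot be told apart from a low level. A difference between the lines was not tested.

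The Y-linked genes were listed at 0 in Pten_Smad4. Of 1556 rows of chromosome Y genes in that table, 1 was above 0 in all 3 libraries (8.43, 13.47 and 10.4 FPKM, a pseudogene of Mid1), so chromosome Y left out of the reference or the counting is argued against, even if those reads came from Mid1 itself. That row was found once older gene symbols were also matched, a step added after matching by current symbols alone had left no such row. Loss of the chromosome in the cells stays open and was not tested.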

How the results depend on the processing

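No paired analysis was possible because the Pten_Smad4 columns carry no replicate number and no test between lines was run. Not run were TMM, the count filters, DESeq2 and limma-voom, which need counts, and the replicate block, an estimated correlation and fry, which need a test. No scaling beyond the library totals is the deposited FPKM itself. The settings on loci and names, copies, centring and thresholds of 5 and 0.5 FPKM were chosen after seeing the data. Against 759 and 506 genes at least 4-fold higher in Pten_Smad4 and RM1, a pseudocount of 0.1 gave 1345 for Pten_Smad4 and a pseudocount of 5 gave 269 and 269; at 2-fold it gave 1546 and 707 in place of 2861 and 1114. At 2-fold in Pten_Smad4, quantile normalization gave 1749 and upper-quartile scaling 1906; median-of-ratios scaling gave 1753 and 1779. With genes of a single table set to 0, 675 and 736 genes in place of 128 and 84 were present in 1 line, 1624 and 1525 were 4-fold higher, and 2318 were 2-fold higher in RM1. The 736 include Eef1a1 and Ftl1, whose Pten_Smad4 loci were left out for carrying several names. Leaving out genes with copies gave 732 at 4-fold in Pten_Smad4 and 296 in RM1. Centring on the median gave 463 at 4-fold in Pten_Smad4, and 1636 and 1757 at 2-fold. Lists above the central 95% numbered 3 in place of 5 without the filter and with genes of a single table set to 0. The log2 ratio of Pten, -0.63, was -0.50 at a pseudocount of 5, -1.11 after quantile normalization and -1.07 after centring; Smad4, 0.02, was -0.41 after centring; Hras, -1.48, was -1.91; and Myc, 3.05, was 2.64, 2.75 and 2.61. In the same order the 4 ratios were -0.996, -0.36, -1.86 and 2.68 after upper-quartile scaling and -1.075, -0.44, -1.95 and 2.60 after median-of-ratios scaling. The causes were not tested. Leaving out each library in turn moved no count past 1.5 times. Among lists with a percentile in the main setting, 7 calls were lost over 4 lists (luminal, mesenchymal, matrix and class I) and 1 was gained (FOXO). Without the filter on low values, 6 lists in place of 5 lay below the central 95%. The added list had too few members for a percentile in the main setting. Among gene ratios 0 of those called changed sign. The depth limits values under about 0.2 FPKM.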

Other observations

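The genes given here were chosen after their values were seen. All lie outside the lists except Spp1, a member of the chemokine and cytokine list that was not among the genes compared. In Pten_Smad4, the acute-phase gene Saa3 was at 111 ± 7.84 FPKM against 0.053 ± 0.092 in RM1, the complement gene C3 at 60.1 ± 6.65 against 0.360 ± 0.104 FPKM, Nos2, which encodes inducible nitric oxide synthase, at 50.6 ± 0.948 against 0.020 ± 0.020 FPKM, and the collagenase gene Mmp13 at 173 ± 7.25 against 0.690 ± 0.061 FPKM. Casp1, the inflammasome protease gene, was at 42.3 ± 2.19 FPKM and listed at 0 in each RM1 library. Fgf7, a growth factor gene of stromal cells, was at 106 ± 7.23 against 0.060 ± 0.052 FPKM.

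In RM1, Cdkn2a, which encodes the inhibitors p16 and p19ARF, was at 30.9 ± 0.834 FPKM, against 0, 0 and 0.158 FPKM in Pten_Smad4, while Trp53, which encodes p53, was at 121 ± 7.27 and 112 ± 4.50 FPKM. Kras was at 22.6 ± 1.88 against 68.3 ± 2.92 FPKM in Pten_Smad4 and Nras at 42.7 ± 0.784 against 37.6 ± 2.26 FPKM. The ribosomal RNA gene Rn18s was at 173, 2012 and 2362 FPKM in RM1 replicates 1, 2 and 3. The locus holding Spp1, which encodes osteopontin, was at 1419 ± 32.3 FPKM in Pten_Smad4 and had no row in the RM1 table used here.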
